A study of Mus musculus with 26 samples.

How the data were processed

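The 12 brown fat libraries of the series were analysed, and the 14 liver samples were not analysed here. The deposited values are read counts per RefSeq transcript, which the authors supplied as whole numbers with no scaling. TopHat2 2.0.8, Cufflinks 2.1.1 and the mm10 genome build are named in the submitters' processing notes, and the counting tool, the annotation version and the filter on listed transcripts are not given in the sources used here. The labels state that RNA was extracted with Trizol and a column kit. Samples were grouped by genotype and by type of RNA (total RNA, IMP2 immunoprecipitate or IgG immunoprecipitate) as the labels give them. The labels match no immunoprecipitate to a total RNA library, and libraries were treated as unpaired. The order of the sample numbers and deviations shared in the counts give a possible match, which was fitted as an alternative.

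The first of the deposited tables, called the knockout table, lists 1579 transcripts in 8 libraries, and the other, called the IgG table, lists 12840 transcripts in 4 libraries. Transcripts without a symbol (117 and 835) were looked up by accession in a RefSeq table for GRCm38.p6, used for names only, which named 114 and 813. The 3 and 22 transcripts left without a name were kept out of library sizes and tests. They took 8.65 to 29.2% of the counts listed per library in the knockout table and 7.39 to 15.8% in the IgG table. For each gene the transcript with the highest summed count was kept, which gave 1189 and 9378 genes. Of these 8 and 217 had counts identical to those of another gene in every library, as transcripts that share reads do. Of 561 genes with high counts in every library of the IgG table, 123 are absent from the knockout table, so the knockout table was not listed by count alone. No sample column of the tables was left unused.

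Summed counts per library are given with the data. They set the counting error of a gene, and intervals for single libraries are exact Poisson intervals at 95%, which cover counting error only. Replicate libraries differed by more than counting error, with a chi-square per degree of freedom of 13.7 to 98.6, and their log2 counts had a Pearson r of 0.943 to 0.979 across genes.

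Counts were scaled by the trimmed mean of M-values (TMM) and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after the edgeR filter on low counts, which removed no gene of the knockout table and left 8966 genes of the IgG table. Standard errors of log2 ratios come from the same models. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Models had 4 residual degrees of freedom in the knockout table, 1 in the IgG table and 6 for the 1189 genes of both tables together, where a term for the table was fitted, and the biological coefficient of variation was 15.3, 24.9 and 16.3%. The IgG group has 1 library, as has the IMP2 immunoprecipitate of the IgG table, and their spread was not measured but is assumed to be that of the other groups. Gene lists of at least 5 members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01 and again with an estimated correlation. In the IgG table, ratios between single libraries were compared with 10000 random lists matched on expression in 20 strata.

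The 26 gene lists, the comparisons, the alternatives and the rule for naming genes were set before the data were examined, and 1 list, the proteasome subunits, was added later. The rule names Igf2bp1, Igf2bp2, Igf2bp3 and Ucp1 where listed, and the 10 largest rises and falls that pass the threshold with groups that do not overlap in CPM, leaving out predicted genes. Where fewer than 5 pass in a direction it names the 5 smallest p-values, and for each list described up to 2 members with the largest and 2 with the smallest values. Igf2bp1 and Igf2bp3 are listed in neither table, and 1 gene that the rule names is not reported here. Alternatives were relative log expression, upper-quartile or library-size scaling, no filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, a change of at least 2-fold, models of the compared groups alone, a smaller prior count, and leaving out each library.

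Methods were tested on simulated data with the dispersion and depth of these libraries. A change of log2 1 was called for 74.6% of changed genes in IMP2-dependent enrichment, for 92.5 to 95.5% in the other comparisons of the knockout table, for 1.64% in the IgG table, and with both tables for 97.0% against total RNA and 74.6% against IgG. A change of log2 0.5 was called for 7.46% of changed genes in IMP2-dependent enrichment and for 23.9 to 35.8% in the other comparisons of the knockout table. False calls numbered 3 to 8 among 989 unchanged genes and 1 among 8689 in the IgG table. A list of 30 genes shifted by log2 0.3 had a camera p of 0.000235, and 3 of 200 unshifted lists had a p under 0.05. Genes were drawn independently there, so this rate does not cover lists whose members vary together. Cytosolic ribosomal proteins, with an estimated correlation of 0.36, are such a list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.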

Results

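RNA recovered with IMP2 from mouse brown fat was measured by RNA immunoprecipitation and sequencing. IMP2, encoded by Igf2bp2, is an RNA-binding protein that attaches to mRNAs and affects their stability and translation. Brown fat burns fuel to make heat through the mitochondrial uncoupling protein Ucp1. The mice were males of 10 weeks on normal chow, kept at 4 °C overnight before tissue was taken, a cold exposure that switches on heat production. Of the 26 samples in the series, 12 are brown fat libraries and 14 are liver samples, which were not analysed here. The deposited counts form a pair of tables that share no library. The knockout table holds total RNA and IMP2 immunoprecipitates of wild-type and Imp2 knockout mice, with 2 libraries in each of the 4 groups. The IgG table holds 2 wild-type total RNA libraries, 1 wild-type IMP2 immunoprecipitate and 1 wild-type immunoprecipitate made with nonspecific IgG. The knockout immunoprecipitate and the IgG immunoprecipitate both measure background recovery.

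After unnamed transcripts were set aside, the summed counts over genes in the knockout table were 2004064 and 1424024 in wild-type total RNA (libraries 16 and 17) and 2489245 and 4916160 in knockout total RNA (18 and 19). They were 1110619 and 780333 in the wild-type immunoprecipitates (21 and 22) and 2382815 and 1890095 in the knockout immunoprecipitates (23 and 24). In the IgG table they were 1466519 and 2701287 in total RNA (15 and 20), 1321756 in the IMP2 immunoprecipitate (25) and 3750103 in the IgG immunoprecipitate (26). The knockout table lists transcripts of 1189 genes and the IgG table of 9378 genes, with all 1189 in both. The knockout table is a selected part of the transcriptome, so its totals are not sequencing depths and its CPM values are relative to the counts of listed genes. All 1579 transcripts listed there had more than 100 counts in each of the 4 wild-type libraries. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these samples.

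Igf2bp2, the deleted gene, had no row in the knockout table, so the knockout label was not checked against its mRNA here. In the IgG table it had 20 and 16 counts in wild-type total RNA, which is 14.1 CPM (95% counting interval 8.58 to 21.7) and 6.04 CPM (3.45 to 9.81). It had 8 counts in the IMP2 immunoprecipitate, or 6.29 CPM (2.72 to 12.4), and 16 in the IgG immunoprecipitate, or 3.91 CPM (2.23 to 6.35). Such intervals cover counting error only, because sequenced copies of one molecule cannot be told apart. The ratio of IMP2 to IgG immunoprecipitate was 1.61-fold (0.596 to 3.99), so a difference was not detectable at this depth.

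The comparison of the wild-type IMP2 immunoprecipitate with wild-type total RNA asks which mRNAs the antibody recovers. Ldhd, a mitochondrial D-lactate dehydrogenase, was higher by log2 1.76 ± 0.14 (SE, n = 2 per group, adjusted p = 0.000208), from 123 ± 7.61 CPM (SD, n = 2) in total RNA to 416 ± 18.4 CPM in the immunoprecipitate. Aldh2, mitochondrial aldehyde dehydrogenase, was higher by log2 1.41 ± 0.14 (adjusted p = 0.000418), and Fh1, the fumarase of the citric acid cycle, by log2 1.07 ± 0.18 (adjusted p = 0.00498). Rps20, a ribosomal protein, was lower by log2 -2.23 ± 0.16 (adjusted p = 0.000208), from 1606 ± 62.2 CPM to 343 ± 8.12 CPM, and Fth1, the ferritin heavy chain, by log2 -1.80 ± 0.34 (adjusted p = 0.00858). Leaving out immunoprecipitate library 22 ended the call of Fth1, at log2 -1.60.

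In all, 118 genes were higher and 148 lower in the wild-type immunoprecipitate at an adjusted p under 0.05. Libraries were treated as unpaired here. A match of immunoprecipitates to total RNA libraries, picked from deviations shared in the counts, gave 311 higher and 335 lower. The other genes with the largest rises were Trap1 (log2 1.27), Fahd2a (1.22), Bcat2 (1.21), Mipep (1.13), Pttg1 (1.13), Isoc2a (1.08) and Mospd3 (1.06). Bcat2 is a branched-chain aminotransferase and Mipep a peptidase that trims proteins imported into mitochondria. Without total RNA library 16 Pttg1 and Mospd3 missed the threshold at 0.91 and 0.87, and without library 17 Bcat2 did at 1.04. Other large falls were Rpl41 (log2 -1.85), Rpl26 (-1.82, with counts identical to those of a copy named Gm15772), Cand2 (-1.74), Rpl32 (-1.62), Rps24 (-1.59), Rps15 (-1.58) and Bag1 (-1.50). Ucp1 was at log2 0.72 ± 0.27 (adjusted p = 0.0878), and its CPM was 5194 and 5489 in total RNA against 6693 and 10860 in the immunoprecipitates. Ucp1 passed the threshold with upper-quartile scaling (log2 0.85), with DESeq2 (log2 0.73) and with that match (log2 0.67). Without immunoprecipitate 21 it was at log2 1.02.

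Among the gene lists, all 20 cytosolic ribosomal protein mRNAs had negative values, with a median of log2 -1.26. Of these 19 fell over all genes tested, all but Rpl13 at log2 -0.57 (adjusted p = 0.0687), and 20 fell when adjusted over the list alone (list adjusted p = 1.65e-15, and adjusted p = 0.241 with an estimated correlation). The citric acid cycle and pyruvate list had a median of log2 0.33, and 4 of its 14 members rose, Fh1 and pyruvate carboxylase Pcx (log2 0.68) among them, or 5 adjusted over the list alone (adjusted p = 0.0032, and adjusted p = 0.289 with an estimated correlation). In the list of mitochondrial import, chaperones and dynamics, 6 of 25 members rose, including the protease Lonp1 (log2 0.84) and the crista organiser Immt (log2 0.74). Adjusted over the list alone 6 rose and 1 fell, with a list median of log2 0.23 (adjusted p = 0.0287, and adjusted p = 0.241 with an estimated correlation). That list missed the threshold without total RNA library 17 (adjusted p = 0.0602) and without immunoprecipitate library 21 (adjusted p = 0.0714).

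Nuclear-encoded subunits of oxidative phosphorylation (OXPHOS), the respiratory chain and ATP synthase, went both ways. The complex I core subunits Ndufs7 (log2 1.02) and Ndufv1 (0.93) were 2 of 4 that rose, and Atp5e (-1.26) and Cox7a2l (-0.99) were 2 of 14 that fell, out of 65, with 5 and 16 adjusted over the list alone and a list median of log2 -0.16 (adjusted p = 0.114). Of 18 fatty acid oxidation genes 2 rose, Acadvl (log2 0.91) and Acads (0.71), both also adjusted over the list alone (list adjusted p = 0.114). In the list of lipogenesis and lipid storage 3 of 18 rose, including G0s2 (log2 1.04) and the fatty acid carrier Fabp4 (1.01), and the same number adjusted over the list alone (list adjusted p = 0.207). Of 44 mitochondrial ribosomal proteins 5 rose and 7 fell, also adjusted over the list alone (list adjusted p = 0.987), and of 12 thermogenic genes only Pank1 (log2 -0.89) and Cox8b (-0.60) fell, also adjusted over the list alone (list adjusted p = 0.987). The split of calls depended on scaling, with 157 higher and 119 lower by library size alone and 214 higher and 94 lower by upper-quartile scaling, which moved the median of all genes by log2 0.14. Leaving out a library gave 32 higher and 61 lower (without total RNA 16), 50 and 85 (17), 79 and 92 (immunoprecipitate 21) and 60 and 85 (22).

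The same comparison in the knockout shows what the antibody recovers where the labels say that IMP2 is absent. Much the same mRNAs stood at the ends. Ldhd was higher in the knockout immunoprecipitate than in knockout total RNA by log2 1.71 ± 0.13 (SE, n = 2 per group, adjusted p = 0.000193), from 128 ± 2.13 to 420 ± 39.9 CPM (SD, n = 2), and Aldh2 by log2 1.16 ± 0.13 (adjusted p = 0.00074). Rps20 was lower by log2 -2.23 ± 0.16 (adjusted p = 0.000193), from 1504 ± 172 to 321 ± 64.9 CPM. Atp5e, the smallest subunit of the ATP synthase stalk, was lower by log2 -1.72 ± 0.14 (adjusted p = 0.000193), from 6995 ± 629 to 2118 ± 40.9 CPM. Ucp1 was at log2 0.28 ± 0.27 (adjusted p = 0.464), with 5979 and 5758 CPM in total RNA against 5559 and 8734 CPM in the immunoprecipitates.

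In the knockout 126 genes were higher and 187 lower, unpaired, against 338 and 348 with libraries matched by deviations shared in the counts. Further genes at the top were Mospd3 (log2 1.29), Bcat2 (1.20), Mipep (1.18), Pttg1 (1.08), Fabp4 (1.06), Ivd (1.06), G0s2 (1.02) and Cfl1 (1.01), where Ivd breaks down leucine in mitochondria. Fabp4 missed the threshold without knockout total RNA 18 (log2 0.86) or without immunoprecipitate 24 (log2 1.0), and G0s2 without total RNA 18 (log2 0.96). At the bottom were Rpl41 (-1.84), Rpl32 (-1.81), Fth1 (-1.77), Cand2 (-1.70), Rps15 (-1.70), H2afj (-1.63), Rpl26 (-1.62) and Pfdn5 (-1.56). All 20 ribosomal protein mRNAs fell, also adjusted over the list alone, with a median of log2 -1.29 (list adjusted p = 1.51e-15, and adjusted p = 0.126 with an estimated correlation). Of 65 OXPHOS mRNAs 5 rose, such as Ndufs7 (log2 0.81), and 27 fell, such as Ndufa3 (-1.14), or 6 and 33 adjusted over the list alone. The OXPHOS list median was log2 -0.38 (adjusted p = 9.22e-05, and adjusted p = 0.126 with an estimated correlation). Of 14 citric acid cycle genes 7 rose, Idh3b (log2 0.85) and Fh1 (0.78) among them, or 8 adjusted over the list alone, with a median of log2 0.49 (adjusted p = 0.000295, and adjusted p = 0.164 with an estimated correlation). Of 25 import and chaperone genes 7 rose, such as Immt (log2 0.82) and Timm10 (0.78), and 2 fell, or 9 and 2 adjusted over the list alone, with a median of log2 0.22 (adjusted p = 0.0108, and adjusted p = 0.126 with an estimated correlation).

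Calls made in both genotypes numbered 77 for higher genes, where 12.5 would be shared by independent lists, and 124 for lower genes, where 23.3 would be. Across the 1189 genes, which are not independent replicates, the log2 ratios of the wild type and the knockout had a Pearson r of 0.904. Their Spearman rho was 0.880, and these comparisons share no library. Listed genes end at log2 -0.30 for the wild-type minus the knockout ratio, so the listing itself ties these ratios. Independent lists are therefore no fair baseline, and the shared calls and r do not describe unlisted genes. By library size alone the knockout gave 246 higher and 145 lower genes, with a shift of log2 0.13 in the median of all genes, and by upper-quartile scaling 273 and 130, with a shift of 0.17. Leaving out a library gave 47 higher and 99 lower genes (without total RNA 18), 74 and 110 (immunoprecipitate 23) and 48 and 87 (24), and without total RNA 19 the number of higher genes was 81.

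**Figure D1:**
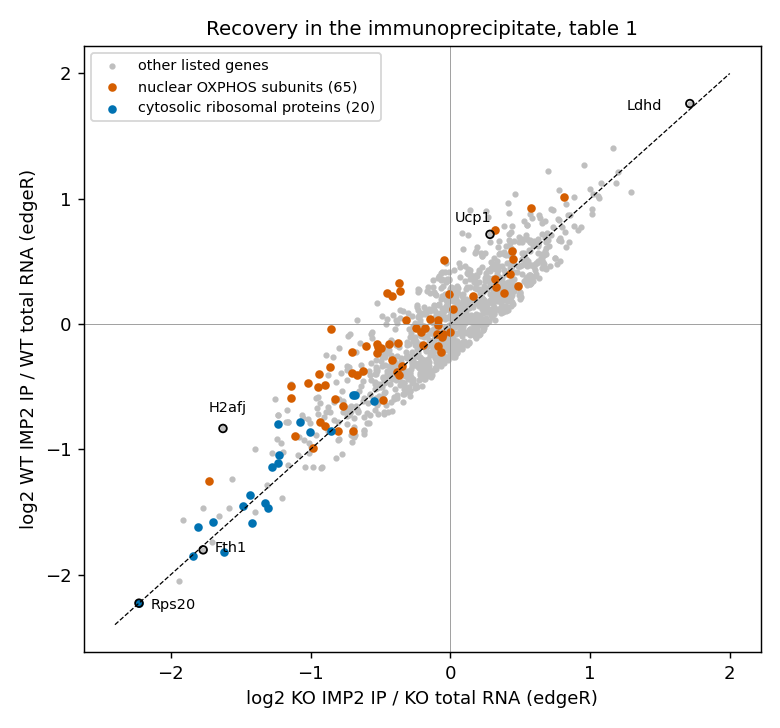
Each point is 1 of the 1189 genes of the knockout table, with log2 of the knockout IMP2 immunoprecipitate over knockout total RNA on the x axis and the same for the wild type on the y axis (edgeR estimates, n = 2 libraries per group). Orange points are nuclear OXPHOS subunits, blue points are cytosolic ribosomal proteins, the dashed line marks equal values, and the cloud ends along a line a little below it, where wild-type recovery would be lower than knockout recovery by more than log2 0.3.

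The difference between these ratios, wild-type immunoprecipitate over total RNA divided by knockout immunoprecipitate over total RNA, measures recovery that depends on IMP2, and the 4 groups of the knockout table allow it. mRNAs of OXPHOS subunits lay above the other listed genes in this measure, with a median of log2 0.20 and 50 of 65 members above 0 (list adjusted p = 9.22e-08, and adjusted p = 0.0481 with an estimated correlation). Atp5k was at log2 0.81 ± 0.35 (SE, n = 2 per group), Ndufb7 at 0.70 ± 0.31 and Atp5o, a subunit of the ATP synthase stalk, at 0.54 ± 0.15, while Cox8a was at -0.16 and Sdha at -0.18 (all adjusted p = 0.999). Atp5o fell in both immunoprecipitates relative to total RNA, from 1688 ± 85.9 to 1281 ± 119 CPM (SD, n = 2) in the wild type and from 1959 ± 107.6 to 1021 ± 10.5 CPM in the knockout. Ucp1 was at log2 0.43 ± 0.38 (adjusted p = 0.999).

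No single gene passed the threshold for this measure with edgeR, with DESeq2 or with limma-voom, and 29 genes had an unadjusted p under 0.05 with edgeR, all with positive values. The smallest p-values belonged to the histone variant H2afj (log2 0.79 ± 0.21), Atp5o, the mitochondrial ribosomal protein Mrpl54 (0.64 ± 0.20), the mitochondrial hydrolase Hint2 (0.77 ± 0.25) and Tmem160 (0.65 ± 0.21), and on the negative side to Agpat6 (-0.29), Acat2 (-0.30), Plbd2 (-0.28), Acot13 (-0.29) and Sdhaf1 (-0.29). Hint2 CPM was 849 ± 28.3 and 1598 ± 423 in wild-type total RNA and immunoprecipitate, against 741 ± 99.7 and 815 ± 12.1 in the knockout (SD, n = 2). The lists of mitochondrial ribosomal proteins (median log2 0.09, adjusted p = 0.224), cytosolic ribosomal proteins (0.09, adjusted p = 0.715), citric acid cycle (-0.11, adjusted p = 0.53) and thermogenic genes (-0.07, adjusted p = 0.921) were not called, and no member of the OXPHOS list or of these lists passed when adjusted over the list alone. Muscle markers, at a median of log2 0.25 over 9 genes, had the opposite direction in the list test (adjusted p = 0.871). All values lay between log2 -0.30 and 0.81, with 69 genes between -0.30 and -0.25 and none below, against 138 above 0.3. The list test therefore compares OXPHOS mRNAs with other listed genes only, in a table whose values of this measure end at that lower edge, by a rule not given in the sources used here. The same edge leaves out larger negative values, so the positive sign of all 29 genes does not show a direction.

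**Figure D2:**
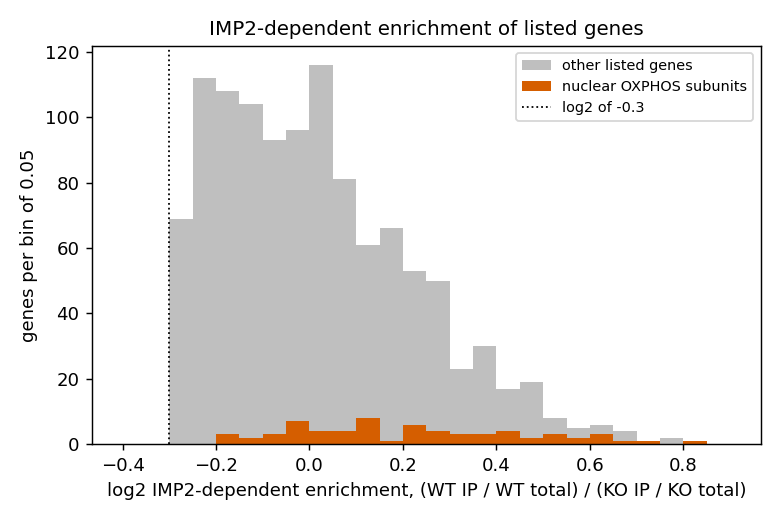
Number of the knockout table genes (y axis, bins of log2 0.05) by IMP2-dependent enrichment (x axis, log2 of the wild-type over the knockout ratio of immunoprecipitate to total RNA, n = 2 libraries per group), with 65 nuclear OXPHOS subunits in orange drawn over the other genes in grey. The dotted line is at log2 -0.3, where the distribution ends, and the median of the OXPHOS subunits is log2 0.20.

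The direct comparison of wild-type with knockout immunoprecipitates does not correct for the level of an mRNA in the tissue. H2afj stood at log2 0.96 ± 0.15 (SE, n = 2 per group) with 167 ± 6.44 against 86.1 ± 14.9 CPM (SD, n = 2), Hint2 at 0.97 ± 0.18, and Cdk11b (0.69), Tmem160 (0.77) and Ap2s1 (0.72) followed. On the negative side were Rps3 (-0.71), Ahnak (-0.64), the translation repressor Eif4ebp1 (-0.80), the acetyl-CoA carboxylase Acacb (-0.46) and the mitochondrial transporter Abcb8 (-0.64), all with adjusted p = 0.129. Ucp1 was at log2 0.30 ± 0.27 (adjusted p = 0.582), and at -0.09 without wild-type library 22 and -0.03 without knockout library 23. No gene passed the threshold with edgeR or limma-voom, 123 genes had positive and 88 negative values at an unadjusted p under 0.05 with edgeR, and DESeq2 called 60 higher and 33 lower. Without knockout immunoprecipitate 23 edgeR called 1 gene higher.

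OXPHOS subunits were higher as a list in this comparison, with a median of log2 0.10 (adjusted p = 0.0457, and adjusted p = 0.728 with an estimated correlation), and 2 members passed when adjusted over the list alone. Ndufa5 (log2 0.96) and Ndufb7 (0.80) had its largest values. The list missed the threshold without any 1 of total RNA 16 (adjusted p = 0.0539) and 17 (0.054), immunoprecipitates 21 (0.0692), 22 (0.165), 23 (0.182) and 24 (0.0508), and by library size alone (0.0545). Lipogenesis and lipid storage genes were lower as a list, with a median of log2 -0.20 (adjusted p = 0.0242, and adjusted p = 0.741 with an estimated correlation), with Acly at -0.77 and the fatty acid synthase Fasn at -0.68 and 2 members lower adjusted over the list alone. That list missed the threshold without immunoprecipitates 22 (0.165) or 24 (0.122). Skeletal muscle markers had a median of log2 2.16 over 9 genes, such as Tcap and Tnni2 at 2.68 each (adjusted p = 0.00793, and adjusted p = 0.949 with an estimated correlation), and none passed adjusted over the list alone. The muscle list missed the threshold without immunoprecipitates 22 (0.184) or 23 (0.182).

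Total RNA of knockout and wild-type brown fat was compared for changes in mRNA level. Mbnl2, a splicing regulator, stood at log2 -0.98 ± 0.17 (SE, n = 2 per group, adjusted p = 0.201), with 281 ± 4.78 CPM in the wild type and 142 ± 28.9 in the knockout (SD, n = 2). Ndn (-0.75), Adhfe1 (-0.70), Cacybp (-0.89) and Actn4 (-0.66) followed with the same adjusted p. Stx4a (log2 0.68, adjusted p = 0.235), Rps3 (0.64), the lysosomal protease Ctsd (0.67), Sod1 (0.48) and Gpihbp1 (0.71) led the positive side, the last 4 with adjusted p = 0.257. Ucp1 mRNA was at log2 0.14 ± 0.27 (adjusted p = 0.891), with 5342 ± 208 CPM in the wild type and 5868 ± 156 in the knockout. Dio2, which activates thyroid hormone in cold-exposed brown fat, had 371 and 350 CPM in the wild type and 58.3 and 523 CPM in the knockout, a spread within the knockout larger than any difference between genotypes.

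No gene passed the threshold for genotype with edgeR or limma-voom. At an unadjusted p under 0.05 edgeR gave 74 positive and 58 negative genes, and DESeq2 called 18 higher and 17 lower. With the spread taken from these groups alone edgeR called 1 gene lower. Skeletal muscle markers were lower in the knockout libraries as a list (median log2 -1.98 over 9 genes, adjusted p = 0.000197, and adjusted p = 0.797 with an estimated correlation), with Tcap at -2.36 and Atp2a1 at -2.30, and missed the threshold without knockout library 18 (adjusted p = 0.135). Ckm, the muscle creatine kinase, had 577 and 1918 CPM in wild-type and 113 and 398 CPM in knockout total RNA. No muscle marker passed over all genes or adjusted over the list alone. Lipogenesis and lipid storage genes were higher as a list (median log2 0.21, adjusted p = 0.0215, and adjusted p = 0.72 with an estimated correlation), with Acly at 0.78 and 2 members higher adjusted over the list alone. Without total RNA 16 this list had an adjusted p of 0.0545 and without total RNA 19 of 0.412. OXPHOS mRNAs had a median of log2 0.09 (adjusted p = 0.0502), with none called over all genes or over the list alone.

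**Figure D3:**
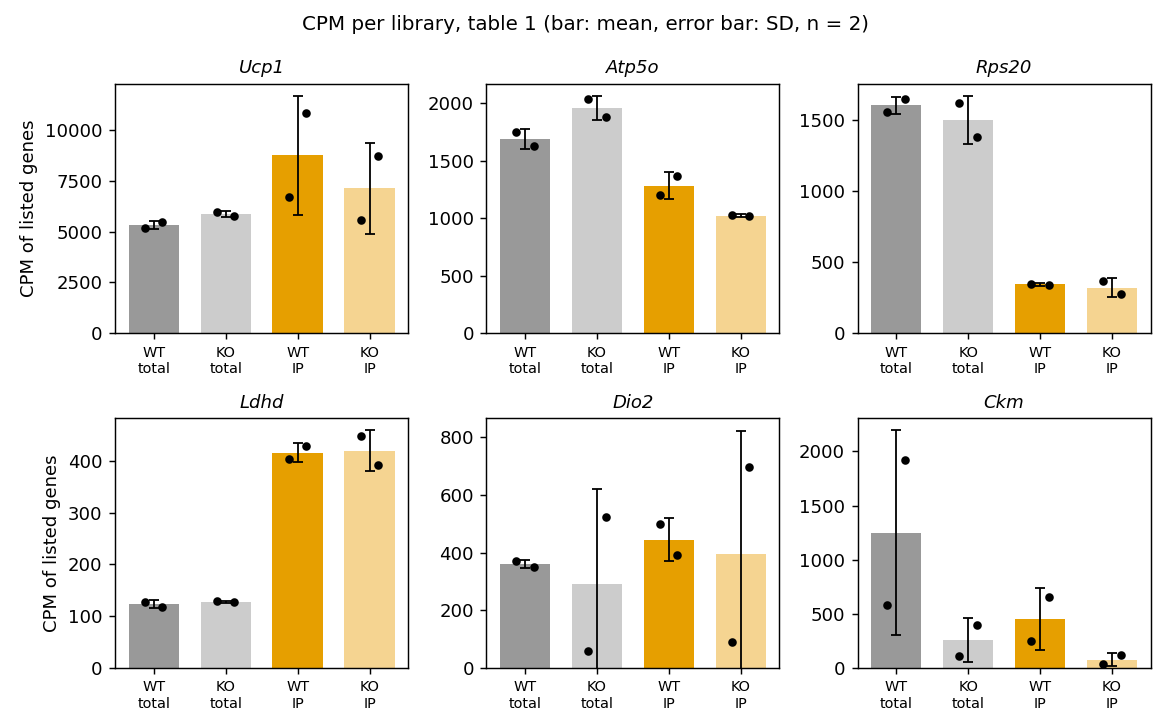
CPM of listed genes (y axis) for 6 genes in wild-type and knockout total RNA and IMP2 immunoprecipitates of the knockout table, with a point per library, bars for the mean and error bars for the SD (n = 2 libraries per group), drawn only above 0. Ldhd and Rps20 differ between immunoprecipitate and total RNA in both genotypes, and the Ucp1 immunoprecipitate libraries lie between 5559 and 10860 CPM.

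The IgG table repeats the wild-type comparison in other libraries with many more genes, where the 1 immunoprecipitate is assumed to vary like the total RNA libraries. Mospd3, a membrane protein of the endoplasmic reticulum, was higher in the IMP2 immunoprecipitate than in total RNA by log2 2.27 ± 0.41 (SE, 1 against 2 libraries, adjusted p = 0.000163), Lars2 by 1.82, the collagen gene Col6a1 by 1.53 and the chloride channel gene Ano1 by 1.91, which were all 4 genes called higher. Lars2 took 33978 and 28732 CPM in total RNA and 111420 CPM in the immunoprecipitate. Of the 77 genes called lower, Srgn (log2 -3.81), Lum (-3.47), Neb (-3.42), Ngly1 (-3.42), Rdx (-3.35), Sar1b (-3.32), Ifit1 (-3.17), Brp44l (-3.15), Mir703 (-3.02) and Postn (-2.96) fell most. Lum and Postn encode matrix proteins and Neb a giant muscle protein. Igf2bp2 was at log2 -0.61 (adjusted p = 0.925) and Ucp1 at 0.29 (adjusted p = 0.931).

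Rplp0 (log2 -1.96) was the 1 of 58 ribosomal protein mRNAs there that fell, also adjusted over the list alone, with a median of log2 -0.64. Of 39 lipid genes 3 fell, including Elovl6 (log2 -2.05) and Agpat2 (-1.99), and the same number adjusted over the list alone. Of 26 muscle markers 4 fell, or 8 adjusted over the list alone, with a median of log2 -0.83. No OXPHOS mRNA of 82 was called, over all genes or over the list alone. The test had 1 residual degree of freedom over 8966 genes, and DESeq2 called 2 higher and 20 lower, without Col6a1, Ano1, Srgn, Lum, Ngly1, Sar1b, Ifit1, Brp44l, Mir703 and Postn. With no filter on low counts Lars2 (log2 1.83), Ngly1 and Brp44l were not called.

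Wild-type recovery in the knockout table returned in the separate libraries of the IgG table. Of the 118 genes higher in the knockout table, 117 (99.2%) had a positive log2 ratio of immunoprecipitate to total RNA in the IgG table, and of the 148 lower genes 140 (94.6%) a negative one. Across 1189 genes, which are not independent replicates, r was 0.781 and rho 0.776. IMP2-dependent enrichment in the knockout table and the log2 ratio of IMP2 to IgG immunoprecipitate in the IgG table had r 0.264 and rho 0.253 across genes, and r was 0.0853 without wild-type immunoprecipitate 22 and 0.144 without total RNA 16. With both tables in 1 model, which gives 4 wild-type total RNA and 3 IMP2 immunoprecipitate libraries, 167 genes were higher and 172 lower. Ldhd (log2 1.52 ± 0.16, adjusted p = 0.000216), Mospd3 (1.49), Aldh2 (1.32), Mipep (1.06), Endog (1.06), Fahd2a (1.05), Ivd (1.03), Trap1 (1.01), D2Wsu81e (0.97) and Pttg1 (0.97) rose most. Fth1 (log2 -2.04 ± 0.34, adjusted p = 0.00187), Rps20 (-1.87), Rpl41 (-1.55), Rpl32 (-1.53), Cand2 (-1.48), Rpl26 (-1.48), Bag1 (-1.34), Rps21 (-1.23) and Apoc1 (-1.23) were among those that fell most.

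In the joint model Ucp1 was at log2 0.50 ± 0.22 (adjusted p = 0.0996), and it passed with upper-quartile scaling (log2 0.61) and with DESeq2 (log2 0.50). All 20 ribosomal protein mRNAs fell, 6 of 14 citric acid cycle mRNAs rose, and 4 of 65 OXPHOS mRNAs rose and 16 fell, or 20, 6, 4 and 19 adjusted over the list alone. Library size alone gave 232 higher and 127 lower genes, and upper-quartile scaling 278 and 116. Without any 1 of total RNA 16 and 17 and immunoprecipitates 21, 22 and 25 the higher genes numbered 92 to 111, and the lower genes 113 without total RNA 16 and 100 without immunoprecipitate 25.

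The comparison with IgG, the background of a nonspecific antibody, has 1 IgG library, which is assumed to vary like the other groups. A gene above IgG need not depend on IMP2. Mospd3, the largest rise here, was also among the genes highest over total RNA in the knockout immunoprecipitate, where the labels say that IMP2 is absent. In the joint model Mospd3 was higher in the IMP2 immunoprecipitates by log2 2.65 ± 0.38 (SE, 3 against 1 library, adjusted p = 0.0109), with 178, 235 and 294 CPM against 36.5 CPM, and the antioxidant enzyme Gpx1 by 1.01 ± 0.20 and Mfge8 by 1.09 ± 0.21 (both adjusted p = 0.0304). The remaining 1 of the 4 genes called higher was 2010107E04Rik, named after its values were seen. Of the 15 lower genes, Macf1, a giant cytoskeletal linker, was lower by log2 -2.03 ± 0.23 (adjusted p = 0.0029), with 267, 191 and 225 CPM against 1080 CPM. Ahnak (-1.45), Dgkd (-1.37), Ubr4 (-1.26), Xrcc6 (-1.21), the lipogenic regulator Mlxipl (-1.19), Anp32a (-1.16), Parp6 (-1.15), Spef1 (-1.12) and Bag1 (-1.07) were other lower genes, as was C130074G19Rik (-1.46), named after its values were seen. Ucp1 was at log2 0.07 ± 0.36 (adjusted p = 0.958) and at -0.11 without immunoprecipitate 22. OXPHOS mRNAs had a median of log2 0.24, with 50 of 65 positive and none called over all genes or over the list alone. Without immunoprecipitate 25 no gene was called, without 22 there were 2 higher and 5 lower, Gpx1 (log2 0.98) and Bag1 (-1.08) were lost without 21 as well, and DESeq2 called 49 and 55.

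Within the IgG table alone the 1 IMP2 and 1 IgG library were compared as ratios, with no test made. Ucp1 had 6917 CPM in the IMP2 immunoprecipitate and 6398 CPM with IgG. That is a ratio of 1.08-fold (1.06 to 1.11, counting error only) or log2 0.11, which turned to -0.07 by library size alone. The OXPHOS median was log2 0.41 over 82 mRNAs, at percentile 95.3 of 10000 random lists matched on expression, and that of 73 mitochondrial ribosomal proteins was 0.32, at percentile 99.6. Skeletal muscle markers had the same median as the OXPHOS list, log2 0.41 over 26 mRNAs (percentile 92.3), and in the joint model log2 0.31 with 8 of 9 positive and none called over all genes or over the list alone. Lipogenesis and lipid storage mRNAs had a median of 0.03, at percentile 0.53, and citric acid cycle mRNAs 0.13, at percentile 3.1. Published targets of the IMP family, also a list set before, had a median of -0.08 over 18 mRNAs, at percentile 15.1. The 4 of them in the knockout table, too few for the list test, had a median IMP2-dependent enrichment of log2 -0.05, with 1 above 0. Among 2075 genes of at least 61.3 CPM in total RNA, the 1129 listed in the knockout table had a median of log2 0.32 against 0.12 for the others, where random lists matched on expression gave 0.24 to 0.28. These percentiles describe single libraries.

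**Figure D4:**
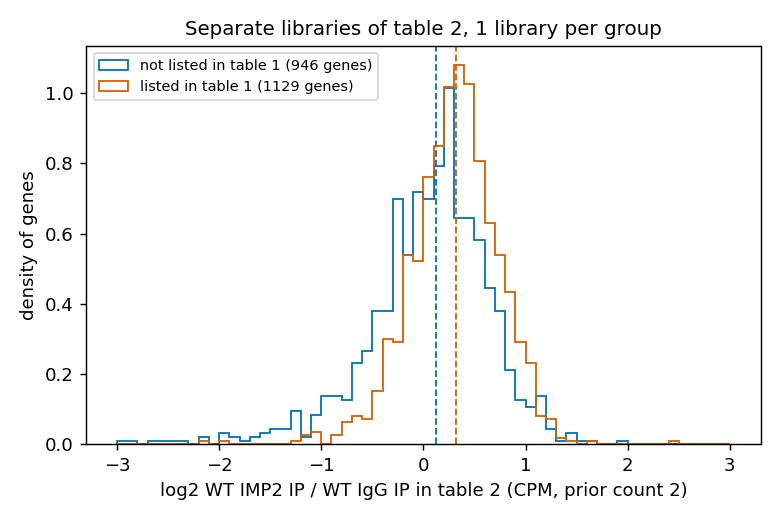
Density of genes (y axis) by log2 ratio of the wild-type IMP2 over the wild-type IgG immunoprecipitate in the IgG table (x axis). The ratio is of CPM with a prior count of 2, with 1 library per group. Genes of at least 61.3 CPM in total RNA are drawn, listed in the knockout table or not, and are not matched on expression. Dashed lines mark the medians. The median is log2 0.32 for listed genes and 0.12 for the others.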

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

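The tests of chance placement of a list, of gene size, of the selection of transcripts and of IgG recovery in this part were set before their results were seen. The proteasome list, the ratio in the knockout for ribosomal protein mRNAs and the lists matched on gene size in the IgG table were chosen after.

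The OXPHOS mRNAs stood above the other listed genes in the difference between genotypes, by a list test that compares them with those genes. The median log2 enrichment was 0.20 over 65 genes, with no single gene called. Part of it came from total RNA. List medians were log2 0.10 for wild-type over knockout immunoprecipitates and 0.09 for knockout over wild-type total RNA. The wild-type immunoprecipitate had a list median of log2 -0.16 against wild-type total RNA. Lists of the same size and expression argue against a random pick of listed genes, since the median enrichment lay at percentile 100 of 10000 such lists. They keep the libraries as they are, so they cannot tell whether differences between libraries by chance moved these mRNAs together. Lists matched on genomic span as well argue against gene size as the whole cause, at percentile 100 too, with a random median of 0.04. Enrichment and log span still had a Spearman rho of -0.37 across genes, which are not independent replicates. What stays open is the selection of transcripts in the knockout table, which may have raised the list, and differences between libraries by chance. Binding by IMP2 stays open too, as does transcript length itself, which was not tested. In the separate libraries of the IgG table, where that selection plays no part, the OXPHOS median lay at percentile 95.3 of matched lists for IMP2 over IgG, inside their central range, and at 97.8 with lists also matched on gene size. Against total RNA the list was low in both, with a median of log2 -0.11 for IMP2 (percentile 2.44, or 1.06 matched on gene size) and -0.48 for IgG (percentile 0.17), so the ratio of IMP2 to IgG rests on a lower recovery with IgG.

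Proteasome subunits, a list added after the values were seen and tested on the same values, had a median log2 enrichment of 0.25, 15 of 17 values above 0 and a camera p of 0.00167, or 0.196 with an estimated correlation. Psmb3 (log2 0.65) and Psmb6 (0.47) had the largest values. Over 45 proteasome mRNAs the IgG table gave a median of log2 0.11 for IMP2 over IgG, at percentile 54.8 of matched lists.

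Ribosomal protein mRNAs were low in the wild-type IMP2 immunoprecipitate. The 20 listed in the knockout table were as low in the knockout, with a median of log2 -1.29 against total RNA. Their low recovery was thus seen where the labels say that IMP2 is absent. Listed genes end at log2 -0.30 for the difference between genotypes, so mRNAs lost only with IMP2 would not be listed. The knockout therefore cannot decide on such a loss for ribosomal protein mRNAs outside that table. A recovery bias common to immunoprecipitates may explain the low recovery. With IgG the list lay at percentile 0 of matched lists against total RNA, with a median of log2 -0.84 over 60 mRNAs. No biological explanation was tested beyond IMP2 itself.

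Spef1, a microtubule-binding protein, had 368 CPM in wild-type total RNA library 20, apart from 269.5 to 285 CPM in the other 3 wild-type total RNA libraries. This was the only 1 of 34 genes tested with a library so far from the rest, and chance gives about 5% of such groups.

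A noncoding transcript that has no name in the table, and was kept out of all tests, took 13.6 and 17.6% of the listed counts in the wild-type IMP2 immunoprecipitates against 8.60 and 9.18% in the knockout immunoprecipitates. In total RNA it took 12.3 and 29.1% in the wild type and 11.5 and 12.7% in the knockout. In the IgG table its share was 7.35% with IMP2 and 9.94% with IgG, so the higher share did not recur there.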

How the results depend on the processing

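Matching each immunoprecipitate to a total RNA library, and lists matched on gene size, were chosen after seeing the data, and the other alternatives were planned. Of the values for whole comparisons under alternatives, 232 kept their side of the threshold or stayed near the main value, 35 weakened, 18 strengthened and 19 moved, with none reversed. For named genes and lists 1768 kept direction and side, 69 weakened, 31 strengthened and 5 reversed. The numbers kept include filter settings that left the knockout table unchanged, whose values were the same by construction. Where no cause is given, the cause was not tested.

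With DESeq2, wild-type against knockout immunoprecipitates gave 60 higher and 33 lower genes instead of none, and wild-type recovery 192 higher and knockout recovery 220. Knockout against wild-type total RNA gave 18 and 17 instead of none, the wild-type comparison in the IgG table had 2 and 20 instead of 4 and 77, and IMP2 against IgG 49 and 55 instead of 4 and 15. With upper-quartile scaling wild-type recovery had 214 higher and 94 lower genes, knockout recovery 273 higher and both tables together 278 higher. With library size alone knockout recovery had 246 higher, and Ucp1 for IMP2 over IgG in the IgG table turned from log2 0.11 to -0.070. These scalings move all genes together, by log2 0.14 and 0.17 in wild-type and knockout recovery for upper-quartile scaling. With limma-voom and relative log expression scaling all values for named genes and lists (75 and 129) kept their direction and side.

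Asking for a change of at least 2-fold, which by construction keeps fewer genes, left 16 higher and 33 lower in wild-type recovery, 12 and 53 in knockout recovery, and 9 and 27 in both tables together. With the compared groups alone 1 gene was lower in knockout total RNA. With an estimated correlation 11 further list calls and that of the ribosomal protein list (adjusted p = 0.241) were lost, and the OXPHOS list for enrichment kept its call (adjusted p = 0.0481). For the OXPHOS list the estimate was 0.0088, below the preset 0.01, yet its camera p for enrichment rose from 7.68e-09 to 0.00401. A higher correlation does not explain that rise, so these settings differ in more than the correlation. The OXPHOS percentile for IMP2 over IgG was 94.9 with the smaller prior count and 97.8 with lists matched on gene size, against 95.3.

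The labels match no immunoprecipitate to a total RNA library, so they set no paired analysis. A match picked from shared deviations in the counts (r 0.716 in the wild type and 0.802 in the knockout, across genes) gave 311 higher and 335 lower genes in wild-type recovery and 338 and 348 in knockout recovery, against 118 and 148 and 126 and 187 without it, with Ucp1 called in wild-type recovery (log2 0.67) and still no gene called for enrichment. The order of the sample numbers gives the same match, but the labels do not say that it marks a shared animal, so this is a hint from the data and not the design.

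Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 32 to 114 higher and 61 to 150 lower genes in wild-type recovery, 47 to 138 and 87 to 188 in knockout recovery, 92 to 204 and 100 to 209 in both tables together, 0 to 3 and 0 to 14 for IMP2 against IgG, and 0 to 1 higher between immunoprecipitates. The adjusted p of the OXPHOS list for enrichment ran from 8.72e-08 to 0.000127 and that of the ribosomal protein list from 1.6e-16 to 9.57e-14. Between the tables r ran from 0.654 to 0.756 and rho from 0.635 to 0.759, the share of higher genes with the same sign from 95.8 to 100% and of lower genes from 83.1 to 98.4%, and r of enrichment with IMP2 over IgG from 0.0853 to 0.292. Ucp1 was called in wild-type recovery without immunoprecipitate 21 (log2 1.02), and, not called, changed sign between immunoprecipitates (-0.094 without wild-type immunoprecipitate 22 and -0.03 without knockout immunoprecipitate 23, up to 0.65), in knockout recovery (-0.058 without immunoprecipitate 24, up to 0.62) and against IgG (-0.11 without immunoprecipitate 22, up to 0.42).

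The filters remove no gene of the knockout table, so they test nothing there. Leaving out a total RNA library of the IgG table was not run for its test, which would have 0 residual degrees of freedom. Simulated changes of log2 2 were called for 49.2% of changed genes in the IgG table and 100% in the knockout table, which differ in depth, libraries, spread and genes tested at once, so the part of depth was not tested. Depth limits Igf2bp2, where 8 and 16 counts leave its ratio of IMP2 to IgG between 0.596 and 3.99.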

Other observations

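The shares of lists among the listed genes, the comparison of listed with other genes and the proteasome list were tests chosen after the result was seen, and the count of splits over all libraries was planned, with that within tables added later.

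Some lists lay at the ends of the ratio of IMP2 to IgG immunoprecipitate in the IgG table, which has 1 library of each. Macrophage and leukocyte markers had a median of log2 0.54 over 15 genes (percentile 99.9 of matched lists), such as the complement gene C1qa with 78.6 CPM for IMP2 and 25.2 CPM for IgG. Smooth muscle and pericyte markers had 0.53 over 14 (percentile 99.9) and replication-dependent histones 0.51 over 15 (percentile 99.8). Nuclear-retained noncoding RNAs had -0.63 over 10 (percentile 0.25), Malat1 among them with 181 CPM for IMP2 and 658 CPM for IgG. Translation initiation and elongation factors had -0.14 over 60 (percentile 0.62). Other cell type markers lay between, the endothelial at percentile 44.9, erythroid 57.4, Schwann and neuronal 23.6, preadipocyte 78.6, white adipocyte 59.5 and skeletal muscle 92.3. Against total RNA, IgG held less of the macrophage (log2 -0.70, percentile 0.05) and histone (-0.57, percentile 0.45) mRNAs, and the smooth muscle markers lay at 0.16 (percentile 69.1).

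Extracellular matrix mRNAs were low in both immunoprecipitates of the IgG table relative to total RNA, with a median of log2 -0.31 over 41 genes for IMP2 (percentile 0.17) and -0.46 for IgG (percentile 0.02). Skeletal muscle markers were low as well, at -0.74 and -1.04 over 26 genes (both percentile 0). Neb had 98.4 and 39.3 CPM in total RNA, 6.29 CPM with IMP2 and 25.6 CPM with IgG. Citric acid cycle mRNAs were high with both, at log2 0.36 (percentile 99.9) and 0.26 (percentile 99.96).

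OXPHOS genes were over-represented among the genes listed in the knockout table, with 65 of 72 genes of sufficient expression listed, or 90.3%, against 76.4% of random lists matched on expression (adjusted permutation p = 0.0114). Mitochondrial ribosomal proteins had 42 of 46 listed (91.3% against 60.9%, adjusted permutation p = 0.0038) and proteasome subunits 17 of 20 (85% against 55%, adjusted permutation p = 0.039), while muscle markers had 9 of 26 (34.6% against 65.4%, adjusted permutation p = 0.0076). The permutations draw single genes and take them as independent. Their p-values therefore do not cover lists whose members vary together, such as muscle markers, with an estimated correlation of 0.95 in the knockout table. Expression alone is argued against for OXPHOS genes, at percentile 99.96 of matched lists. A listing that follows IMP2-dependent recovery may explain it, since the listed genes lay at percentile 100 of matched lists for IMP2 over IgG in separate libraries. Over all genes of the IgG table they also lay at percentile 100 for IMP2 over total RNA and 99.3 for IgG over total RNA. Abundance in the immunoprecipitates, with or without IMP2, may therefore have played a part as well. As the only rule it is argued against by the edge of IMP2-dependent enrichment at log2 -0.3. At that edge 69 genes lay within log2 0.05 above and 0 below, while 147 genes lay below -0.3 for wild-type over knockout immunoprecipitates. The rule by which transcripts were listed is not given in the sources used here, so other rules stay open.

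Of the 29 genes with an unadjusted p under 0.05 for enrichment, 29 had a ratio of IMP2 to IgG above 0 in the IgG table and 22 lay above the median of listed genes, where 78.6% of all listed genes lay above 0. Without total RNA 17 there were 15 such genes, 14 above 0, without immunoprecipitate 21 there were 60, 53 above 0, without immunoprecipitate 22 there were 18, 17 above 0, and by library size alone 16, 14 above 0. The number of genes called between wild-type immunoprecipitates and total RNA in both tables was compared over splits of the 7 libraries. Of 35 splits 34 could be fitted, and 1 of them, the real one, gave as many as 339 calls, with 181 for the highest other. The model has a term for the table, so the bound of 5% set before holds only for splits within tables, and these are 18, too few for a share under 5%, with 181 for the highest other.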
